A study of Mus musculus with 27 samples.

How the data were processed

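Gene expression was taken from 27 Affymetrix MG_U74Av2 arrays of total RNA from murine neural crest explants, in the intensity values as deposited. Per the submitters' processing notes the authors made these intensities with RMA (RMA Express, version 0.2), which corrects background, normalises by quantiles and summarises the probes of a probe set, and used GeneSpring as a later step. Whether GeneSpring changed the values is not given in the sources used here. The values were linear intensities, from 3.92 to 17003, and the array medians lay between 92.1 and 100.5. The plan had taken them for log2 values, so log2 was taken once for every analysis. RMA gives no detection calls and compresses differences between dim probe sets, so the level below which a transcript was absent is unknown. No 2 arrays held identical values, and within a group the correlation of log2 values between 2 arrays ran from 0.9677 to 0.9966 across probe sets.

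The table held 12488 probe sets, of which 66 control probe sets were left out and 12422 were tested. One gene symbol stood for 10833 of them, several for 396 and none for 1193, and 8251 genes were named by at least 1 probe set. Symbols followed the array's annotation, and 0 symbols were updated through a gene ID in the mouse gene table of assembly GRCm38.p6. Genome positions were not used here. Where a gene had several probe sets, the one with the highest mean over the 27 arrays stood for it. Signal that a probe set may share with related genes was not tested, for example for Myh7 (98616_f_at), Actg2 (93102_f_at), Cldn7 (99561_f_at) and Spsb1 (161817_f_at).

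Arrays were grouped by title into control and retinoic acid (RA) at 6, 12, 24 and 48 h. The description of 48 h control 3 calls it RA treated, replicate 3, and the same description belongs to 48 h RA 3. It was kept among the controls, and an alternative grouped it with RA. Scanner records gave 9 scan days and 7 chip lots, with 1 lot on each day. A control and an RA array of one time, scanned on one day with consecutive numbers, made 13 record pairs, and 48 h control 2 had no partner. The labels state that each embryo gave a control side and an RA side. They do not state whether equal replicate numbers mark the same embryos. With group means removed, control and RA arrays of equal number correlated across probe sets by 0.466 to 0.503 at 6 h and by 0.229 to 0.642 at 24 h, where the numbers were read as pairs. At 12 h and 48 h they did not correlate above the bound of 0.1 in every case and were not read as pairs. At 12 h, though, equal numbers marked the same arrays as the record pairs. At 48 h they did so for number 1 alone. The record pairs had a median correlation of 0.469 over 13 pairs, and the other 33 combinations of a control and an RA array of one time had a median of -0.253.

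Differences were tested with limma 3.58.1 in R 4.3.3, by 1 linear model over the 8 groups with 19 residual degrees of freedom, empirical Bayes moderation and no block. Differences were tested two-sided, and changes over several times by a moderated F-test. Adjusted p values are Benjamini-Hochberg values within a comparison over all 12422 probe sets, and a result passed at an adjusted p below 0.05. Log2 differences are given with their SE. The p values measure the spread between these arrays. Without a block this spread includes the differences between record pairs. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

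The groups, tests, threshold, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Named genes were the 12 highest and 12 lowest past the threshold in each RA comparison, 6 in each direction for the change of controls from 6 to 48 h, known RA targets, and members of the fixed lists. Of each list these were up to 6 members past the threshold at a time, or the 2 largest changes where no member passed. Probe sets with no or several genes were not named by this rule. Some genes that the rule covers are not reported here. The 26 lists covered retinoid metabolism, Hox and TALE homeobox genes, neural crest, neurons, glia, melanocytes, cartilage and bone, smooth muscle, extracellular matrix, matrix proteases, cell adhesion, Wnt, TGF-beta and BMP signalling, FGF with hedgehog, Notch and ephrin signalling, cell cycle, p53 targets, neural tube epithelium, surface ectoderm, endothelium, blood, macrophages, mesoderm and skeletal muscle, endoderm, immediate early and heat shock genes, glycolysis and cholesterol synthesis. Lists were tested with camera of limma against all other genes, with a preset correlation of 0.01, and p values were adjusted over the 26 lists within a comparison. Alternatives were a correlation estimated from the residuals and all probe sets naming 1 gene in place of 1 per gene.

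Alternatives were a block for replicate number, scan day or record pair, median centring, cyclic loess, leaving out the 30% dimmest probe sets, an intensity trend with robust moderation, array weights, fits to only the groups compared, and leaving out each array. The record pair block, the list tests, the RA target tests and the agreement between times with a scan-day block, the list tests on the time comparisons, the comparison of 24 h with 12 h controls within scan days, the test of 3′ minus 5′ signals between 6 and 48 h controls, and the 24 h fit without scan day 5 were added after seeing the data. Blocks left 13 residual degrees of freedom for scan day and 9 for record pair or replicate number. In simulated data with 200 of 12422 genes changed by 1 log2, the fit recovered 87% at 6 h, 94.5% at 24 h, 93.5% at 48 h and 98% for the mean over times. For a change of 0.5 log2 it recovered 26%, 45.5%, 28% and 76.5%. With no change it called 0 genes in any of these comparisons or at 12 h, where no change was simulated. With a change of 1 log2, 15 of 202 calls at 48 h were false. The simulated values were independent, with no record pairs or scan days, so these numbers cannot be carried over to the real arrays.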

Results

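The series measured transcript levels in murine neural crest explants over the first 2 days of exposure to retinoic acid (RA), the active form of vitamin A, given at 1e-06 M in ethanol. Dorsal neural tubes were bisected along the midline, and one side of each embryo served as control while the other received RA. For the 6 h arrays the explants were first cultured overnight on fibronectin, in DMEM with 10% horse serum. There were 3 control and 3 RA arrays at 6 h, 3 and 3 at 12 h, 4 and 4 at 24 h, and 4 controls and 3 RA arrays at 48 h. Each array gave 12422 probe sets as log2 RMA intensity, and the number of arrays limits the precision. Time in culture, which overlaps with scan day and chip lot, carried 40% of the variance over all probe sets (3 degrees of freedom). RA within a time carried 8.7% (4 degrees of freedom), the record pair after RA 41% (10) and the remaining differences 10.4% (9). The arrays of 6 h and 48 h had scan days of their own, so the share of time cannot be told apart from theirs. The median difference between RA and control over all probe sets lay between -0.004 and 0.026 log2 at the 4 times.

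Genes with a known response to RA served to check the labels, in a set chosen beforehand. The results below cover 8 such genes. Cyp26a1 (98320_at), the cytochrome P450 that degrades RA, had mean control levels of 4.65, 4.66, 4.56 and 4.73 at 6, 12, 24 and 48 h. It had mean RA levels of 5.75, 6.71, 6.99 and 7.0. Its control level lay below the 25th percentile of the array in 14 of 14 controls, where RMA compresses differences, so its changes may be understated. The words "at least" before a change mark this alone and leave sampling error aside. Dhrs3 (102797_at), which reduces retinaldehyde to retinol, went from control means of 5.90, 6.35, 6.16 and 6.18 to RA means of 7.39, 7.68, 7.92 and 8.25. Both passed at all 4 times, and Hoxb1, a homeobox gene of the hindbrain, passed at 24 h. Crabp1 and Crabp2, which bind RA in the cytoplasm, the nuclear receptor gene Nr2f1, the membrane transporter gene Stra6 and the transglutaminase Tgm2 passed at no time. The differences for Crabp1 were 0.16, 0.13, 0.04 and -0.08 log2, and those for Crabp2 were 0.35, 0.05, 0.65 and 0.79. With a record pair block, added after seeing the data, Crabp2 passed at 48 h (0.94, adjusted p = 0.00852), and Hoxb1 passed at 12 h in 3 alternatives given below. Of 32 tests by limma over the 8 genes and 4 times, 9 passed, and 7 to 10 did with 1 array left out. The array titled 48 h control 3, whose description calls it RA treated, had levels of 4.93 log2 for Cyp26a1 and 6.27 for Dhrs3. No RA array lay below 5.63 for Cyp26a1 or 7.36 for Dhrs3. The 48 h comparison called 34 probe sets with this array as a control, 35 without it and 7 with it among the RA arrays.

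**Figure D1:**
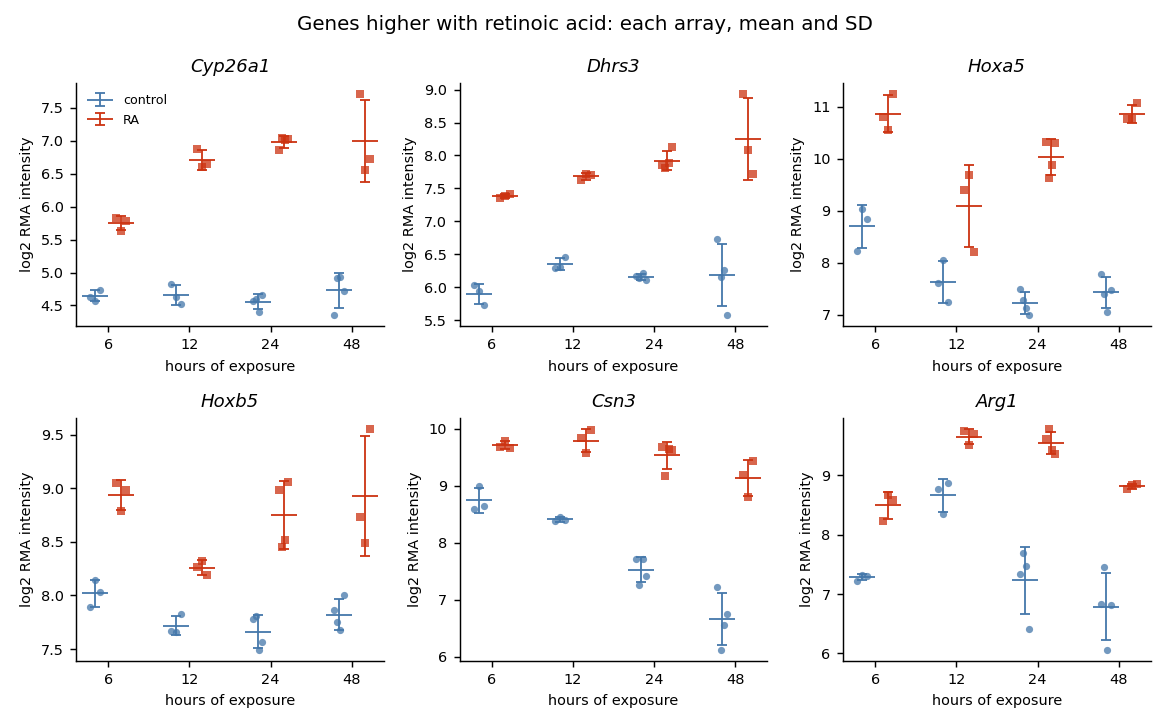
Log2 RMA intensity of Cyp26a1, Dhrs3, Hoxa5, Hoxb5, Csn3 and Arg1 (vertical axes) against hours of exposure (horizontal axes) in control and RA cultures, with a point for each array and the mean and SD of each group. Mean Cyp26a1 stayed between 4.56 and 4.73 in controls and lay at 5.75 to 7.0 with RA.

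The 6 h comparison asked which transcripts differed after the shortest exposure. Hoxa5 (103086_at), a homeobox gene that sets position along the body axis, rose 4.5-fold by 2.17 log2 (SE 0.30), from 8.70 to 10.87. Dhrs3 rose 2.8-fold by 1.48 log2 (SE 0.22) and Cyp26a1 at least 2.14-fold by 1.10 log2 (SE 0.19). All 3 were higher in RA in 3 of 3 record pairs, with adjusted p of 0.0027, 0.00461 and 0.0355 by limma. No other probe set passed in this fit without a block, and none fell in it. In it 533 had an unadjusted p below 0.05, where 621 would by chance if arrays were independent. Over the arrays of all times, record pairs, many of which also differ in scan day, carried 41% of the variance. This fit leaves that share in the spread, and it was not measured for 6 h alone. The Cyp26a1 call was lost without any 1 of the 6 arrays (adjusted p = 0.111 to 0.354) and after cyclic loess (0.199) or median centring (0.0677), and the Dhrs3 call was lost without control 3 (0.0781). The count was 1 without control 3 and 2 without any other. With scan day as a block 55 probe sets passed (16 higher, 39 lower), these 3 among them with adjusted p of 0.00175, 4.07e-08 and 0.0136. Replicate number as a block gave 3 (2 higher, 1 lower), of which 2 were shared, and an adjusted p of 0.212 for Cyp26a1. That block also ties 48 h arrays not read as pairs. A record pair block, with the same pairs at 6 h and added after seeing the data, gave 118 calls (41 higher, 77 lower), the 3 among them. Within scan day 1, with 2 arrays of each group, limma called 0 probe sets and 766 had an unadjusted p below 0.05.

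At 12 h the RA-degrading enzyme Cyp26a1 rose at least 4.14-fold by 2.05 log2 (SE 0.19). Csn3 (99065_at), which encodes the milk protein kappa-casein, rose 2.61-fold by 1.38 log2 (SE 0.21), and Dhrs3 rose 2.51-fold by 1.33 log2 (SE 0.22). Each was higher in 3 of 3 record pairs, with limma adjusted p of 2.87e-06, 0.00463 and 0.0161. Hoxa5 differed by 1.46 log2 (adjusted p = 0.154), Hoxb1 by 1.22 (adjusted p = 0.104) and Fabp7 by -1.07 (adjusted p = 0.543), and these did not pass. Hoxb1 did pass with scan day as a block (adjusted p = 0.00317), array weights (0.00243) or a record pair block (0.0076). Cyp26a1, Csn3 and Dhrs3 were the 3 calls by limma, and 309 probe sets had an unadjusted p below 0.05. Dhrs3 lost its call without any 1 of the 6 arrays (adjusted p = 0.0685 to 0.154) and Csn3 without RA 1 (adjusted p = 0.0523), where 1 call was left. A scan-day block gave 12 calls (10 higher, 2 lower), the 3 included. A record pair block, added after seeing the data, gave 17 (14 higher, 3 lower), again with the 3 included. Within scan day 3, with 2 arrays of each group, limma called 0 and 857 had an unadjusted p below 0.05.

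At 24 h Hoxa5 rose 7.01-fold by 2.81 log2 (SE 0.26) and Hoxb5 (103666_at) by 1.09 (SE 0.17), with limma adjusted p of 6.37e-07 and 0.00181. Hoxb1 (93888_at) rose by 1.03 (SE 0.21) and Hoxc4 (102660_at) by 0.85 (SE 0.16), with adjusted p of 0.0329 and 0.0148. Cyp26a1 rose at least 5.39-fold by 2.43 log2 (SE 0.17) and Dhrs3 3.38-fold by 1.76 (SE 0.19), with adjusted p of 4.94e-09 and 8.84e-06. Arg1 (93097_at), the arginase of the urea cycle, rose 4.96-fold by 2.31 log2 (SE 0.23, adjusted p = 2.01e-06) and Csn3 4.02-fold by 2.01 (SE 0.18, adjusted p = 4.51e-07). A smaller rise was that of Spsb1, a substrate adaptor of a ubiquitin ligase (1.18 log2, SE 0.22, adjusted p = 0.0148). Rin2, a regulator of Rab5 in endocytosis, rose by 1.03 (SE 0.17, adjusted p = 0.00436) and Meox1, a homeobox gene of the somites, by 0.90 (SE 0.16, adjusted p = 0.0133). All of these were higher in RA in 4 of 4 record pairs. Fabp7 (98967_at), a fatty acid binding protein of radial glia, fell by 1.26 log2 (SE 0.23, adjusted p = 0.0148) and was higher in 0 of 4. In all, limma called 19 probe sets, 18 higher and 1 lower, which named 15 genes, and 228 had an unadjusted p below 0.05.

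Several of the 24 h calls were lost with 1 array fewer, while the log2 changes in those fits stayed at 0.84 to 1.07 for Hoxb1, 0.75 to 0.86 for Hoxc4, 1.01 to 1.16 for Spsb1, -1.24 to -1.14 for Fabp7 and 0.81 to 0.86 for Meox1. Hoxb1 lost its call without control 1, 3 or 4 or RA 1, 2 or 4 (adjusted p = 0.0777 to 0.209) and Hoxc4 without control 3 or 4 or RA 1, 2 or 4 (0.0532 to 0.109). Spsb1 lost it without control 2 or 4 or RA 2, 3 or 4 (adjusted p = 0.0603 to 0.105). Fabp7 lost its call without control 2 or 4 or RA 1 or 3 (adjusted p = 0.0554 to 0.0962) and Meox1 without control 1 or 4 or RA 3 (0.068 to 0.0922). The number of calls at 24 h was 10 without control 4 and 12 without RA 3. It was 10 in a fit to the 24 h arrays alone, where Hoxb1, Hoxc4, Meox1 and Spsb1 were lost (adjusted p = 0.0709 to 0.267). Without scan day 5, a fit added after seeing the data, Hoxb1 (0.96, adjusted p = 0.107) and Spsb1 (0.98, adjusted p = 0.243) were lost. Replicate number, which paired the 24 h arrays, gave 31 calls as a block (24 higher, 7 lower) and scan day 50 (44 higher, 6 lower), all 19 among them in both. A record pair block, with the same pairs at 24 h and added after seeing the data, gave 81 (58 higher, 23 lower), again with all 19 among them. Within scan day 3, with 2 arrays of each group, limma called 5. Scan days 4 and 5 held 1 array of each group at 24 h.

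At 48 h Hoxa5 rose 10.8-fold by 3.44 log2 (SE 0.28) and Csn3 5.56-fold by 2.48 (SE 0.19), with limma adjusted p of 4.06e-08 and 3.15e-08. Cyp26a1 rose at least 4.82-fold by 2.27 log2 (SE 0.18), Dhrs3 4.18-fold by 2.06 (SE 0.21) and Arg1 4.07-fold by 2.02 (SE 0.25), with adjusted p of 3.29e-08, 1.87e-06 and 5.32e-05. Krt20 (95621_at), an epithelial keratin, rose by 1.49 log2 (SE 0.23, adjusted p = 0.00131), and Etv2 (101150_at), an ETS factor of endothelial and blood progenitors, by 1.46 (SE 0.31, adjusted p = 0.037). Igfbp3 (95082_at), which binds insulin-like growth factors, rose by 1.36 log2 (SE 0.15, adjusted p = 5.87e-06). Meox1 rose by 1.24 log2 (SE 0.18, adjusted p = 0.000503) and Hoxb5 by 1.10 (SE 0.18, adjusted p = 0.00259). Gas1, a membrane co-receptor for hedgehog proteins, rose by 1.00 log2 (SE 0.17, adjusted p = 0.0032) and Col7a1, the collagen of anchoring fibrils, by 0.87 (SE 0.18, adjusted p = 0.0312). Each was higher in 3 of 3 record pairs. A second probe set of Igfbp3 differed by 0.24 (adjusted p = 1).

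Of the genes that fell at 48 h, Vcam1 (92558_at), a cell adhesion receptor, fell by 1.70 log2 (SE 0.30, limma adjusted p = 0.00438). Cav1 (160280_at), the coat protein of caveolae, fell by 1.16 (SE 0.21, adjusted p = 0.00521) and Dkk1 (99881_at), a secreted Wnt antagonist, fell by 1.13 (SE 0.20, adjusted p = 0.00534). Ccn3 (100507_at), a matricellular protein, fell by 1.08 log2 (SE 0.19, adjusted p = 0.00404) and Lama2 (92366_at), a laminin chain of basement membranes, by 0.74 (SE 0.14, adjusted p = 0.0163). All 5 were higher in RA in 0 of 3 record pairs, and a second probe set of Cav1 differed by 0.02 (adjusted p = 1). In total 34 probe sets passed, 29 higher and 5 lower, which named 29 genes, and 425 had an unadjusted p below 0.05. Etv2 lost its call without any 1 of the 4 controls or RA 1 or 2 (adjusted p = 0.0618 to 0.234), with its change at 0.97 without RA 1, and Col7a1 without control 2 or 3 or RA 1 or 3 (0.085 to 0.182). Lama2 lost it without control 2 (adjusted p = 0.0684), RA 2 (0.12) or RA 3 (0.169), and Cav1 without RA 3 (0.0681). A fit to the 48 h arrays alone called 3 probe sets, with Hoxa5 and Csn3 the named genes left, and array weights called 15, with Vcam1, Cav1, Dkk1, Lama2, Meox1, Krt20, Gas1, Etv2 and Col7a1 lost (adjusted p = 0.0563 to 0.989). With 48 h control 3 grouped as RA 7 passed. Hoxa5 (2.35, adjusted p = 0.2), Csn3 (1.79, 0.129), Dhrs3 (1.60, 0.105) and Arg1 (1.09, 0.343) lost their calls. Igfbp3, Meox1, Hoxb5, Krt20, Gas1, Etv2 and Col7a1 lost theirs too (0.0999 to 0.434), with all the named falls. The array had control levels of Cyp26a1 and Dhrs3, so such losses would follow if its title is right. A scan-day block gave 99 calls (76 higher, 23 lower), the 34 among them. No scan day at 48 h held 2 arrays of each group, so the block, over the 3 days with 1 array of each, was the comparison within days. A record pair block, added after seeing the data, gave 123 calls (91 higher, 32 lower), with 33 of the 34 among them.

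**Figure D2:**
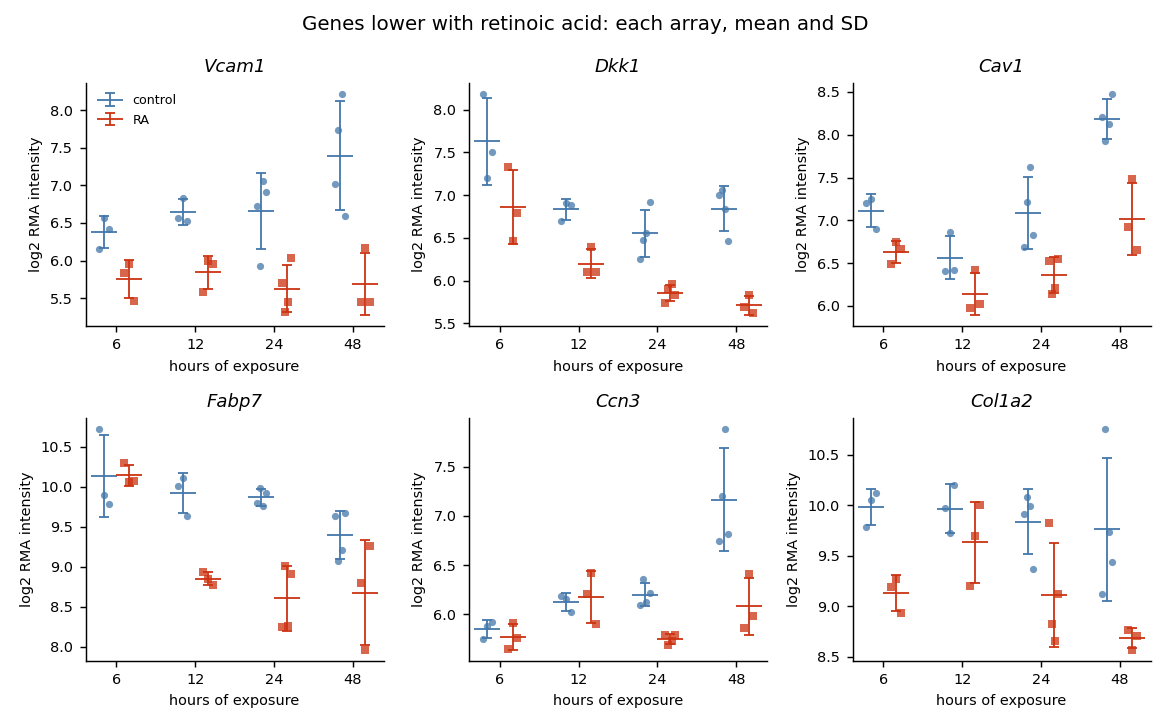
Log2 RMA intensity of Vcam1, Dkk1, Cav1, Fabp7, Ccn3 and Col1a2 (vertical axes) against hours of exposure (horizontal axes) in control and RA cultures, with a point for each array and the mean and SD of each group. At 48 h RA arrays were lower by 1.70 log2 for Vcam1 and by 1.08 for Ccn3.

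Averaged over the 4 times, Hoxa5 rose with RA by 2.47 log2 (SE 0.14), Cyp26a1 by 1.96 (SE 0.09) and Csn3 by 1.71 (SE 0.10), with limma adjusted p of 3.8e-11, 1.19e-12 and 3.8e-11. Dhrs3 rose by 1.66 (SE 0.11) and Arg1 by 1.63 (SE 0.13), with adjusted p of 2.18e-10 and 9.4e-09. Etv2 rose by 1.00 log2, Hoxb5 by 0.91, Hoxb1 and Spsb1 by 0.89, Krt20 by 0.86, Meox1 by 0.82 and Rin2 by 0.80, with adjusted p from 1.2e-06 to 0.000835. These 12 genes were higher in 13 of 13 record pairs. The Wnt ligand gene Wnt11 rose by 0.52 (SE 0.11, adjusted p = 0.0146) and Cdkn2b, an inhibitor of cyclin-dependent kinases, by 0.66 (SE 0.13, adjusted p = 0.0144), both in 13 of 13 pairs. Plat, the tissue plasminogen activator, rose by 0.50 (SE 0.11, adjusted p = 0.0234) and Car2, a carbonic anhydrase, by 0.72 (SE 0.16, adjusted p = 0.0332), each in 12 of 13.

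In the same mean over times, Vcam1 fell by 1.04 log2 (SE 0.15, limma adjusted p = 0.00023) and Meox2, a homeobox gene of the somites and limb muscle, fell by 1.03 (SE 0.22, adjusted p = 0.0205). Dkk1 fell by 0.81 log2 (SE 0.10, adjusted p = 4.35e-05), Col1a2, a chain of type I collagen, by 0.75 (SE 0.15, adjusted p = 0.00974) and Cav1 by 0.70 (SE 0.10, adjusted p = 0.000357). Each of these 5 was higher in 0 of 13 record pairs. A second probe set of Col1a2 differed by 0.14 (adjusted p = 0.999). Levels of Meox2, Ptn and Dlx5 lay below the mean 25th percentile of the arrays in 5, 7 and 6 of the 8 groups. RMA compresses differences there, so the sizes of their changes are uncertain. Smaller falls were those of Fabp7 (-0.76 log2), the matrix proteoglycan Bgn (-0.59), the growth factor Ptn (-0.51), the membrane glycoprotein Tpbg (-0.45), Dlx5, a homeobox gene of the branchial arches (-0.41), the forkhead factor Foxd1 (-0.39) and the endosomal adaptor Tom1l1 (-0.38). Their adjusted p ran from 0.00154 for Fabp7 to 0.0463 for Ptn, and RA was higher in 0 to 2 of 13 pairs. In total 70 probe sets passed, 53 higher and 17 lower, and 699 had an unadjusted p below 0.05. Ptn and Tom1l1 each lost the call in 19 of 27 fits without 1 array (adjusted p = 0.0503 to 0.105 and 0.0516 to 0.105), and Bgn in 15 (0.0503 to 0.0848). Ptn and Tom1l1 also lost it after median centring (0.0609 and 0.0634) and cyclic loess (0.0719 and 0.0655). Meox2 lost it without control 3 (0.0566) or RA 1 (0.051) of 6 h or control 3 (0.0525) or RA 2 (0.0511) of 12 h, and Dlx5 without RA 3 of 6 h (0.0555) or of 12 h (0.0536). With 48 h control 3 grouped as RA, Vcam1 (adjusted p = 0.131), Meox2 (0.131), Col1a2 (0.0657), Bgn (0.138), Dlx5 (0.169), Ptn (0.112) and Tom1l1 (0.0792) lost it. Since that array had control levels of Cyp26a1 and Dhrs3, such losses would follow if its title is right. A block for scan day gave 286 calls (133 higher, 153 lower), the 70 among them. A record pair block gave 365 (157 higher, 208 lower), again with the 70 among them. The mostly higher calls above are thus those of the fit without a block.

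Whether the response differed between times was tested directly. Igfbp3 was the named gene that passed, with an RA effect of -0.32 log2 at 6 h, 0.09 at 12 h, 0.51 at 24 h and 1.36 at 48 h. Its effect at 48 h exceeded that at 6 h by 1.67 (adjusted p = 0.000362 by limma), and the call held without any 1 array. It was lost in a fit to the 6 and 48 h arrays alone (adjusted p = 0.0644) and with 48 h control 3 grouped as RA (1.17, adjusted p = 0.989). The latter loss would follow if that array's title is right. Replicate number as a block also lost the call (adjusted p = 0.0634), but ties 48 h arrays not read as pairs. Scan day or record pair as a block kept the 2 calls of the test of 48 h minus 6 h, this one among them. Of 100 draws of labels within each time, 13 gave as many calls for the F-test and 19 for 48 h minus 6 h, the real ones included. Of 100 that swapped labels within record pairs, 7 did for the F-test and 2 for 48 h minus 6 h. These draws bear on the number of calls and not on Igfbp3 alone. The other call was probe set 161049_at, which names no gene and was singled out after its values were seen. Its effect was 1.47 at 24 h and 3.50 at 48 h, and the difference between 48 and 6 h was 3.07. The difference for Csn3 was 1.51 (adjusted p = 0.0837) and that for Hoxa5 1.26 (adjusted p = 1). The moderated F-test over the 3 later times against 6 h and the test of 48 h minus 6 h each called 2 probe sets, and 129 and 294 had an unadjusted p below 0.05. Without 48 h RA 2 the test of 48 h minus 6 h called 5. With a scan-day block the numbers were 6 and 14. A gene that passed at one time and not at another is otherwise not shown to differ between them.

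Genes of retinoid metabolism and Hox genes were tested as lists. Of 27 measured retinoid genes, Cyp26a1 and Dhrs3 rose at each time and in the mean, where 4 rose when adjusted over the list alone. The camera test of limma put the list above other genes at 12 h (adjusted p = 0.00242, median 0.05 log2) and 24 h (adjusted p = 0.000858, median 0.03), and not at 6 h (adjusted p = 0.222). It did so at 48 h (adjusted p = 0.0462, adjusted p = 0.353 with an estimated correlation) and in the mean over times (adjusted p = 0.00416, adjusted p = 0.106 with an estimated correlation). At 48 h the list's median was -0.02 while its mean was 0.17 and its test pointed upward. Of 40 measured Hox, TALE and related homeobox genes, Hoxa5, Hoxb5, Hoxb1, Hoxc4 and Hoxb4 rose in the mean over times, and adjusted over the list alone 7 rose and 1 fell. Hoxb4, named after its value was seen, rose by 0.49 log2 (adjusted p = 0.000466). The list lay above other genes at 6, 12, 24 and 48 h and in the mean, with adjusted p of 0.00141, 0.011, 7.93e-05, 0.0202 and 1.85e-05. These calls were lost, with adjusted p = 0.511, 0.681, 0.321, 0.603 and 0.175 with an estimated correlation. The list's medians were 0.06, 0.06, 0.02, 0.01 and 0.03 log2. With scan day as a block the adjusted p for 48 h was 0.142 for Hox genes and 0.052 for retinoid genes, and the other calls of these lists held. Within scan days the Hox medians ran from -0.03 to 0.11 at 6 h, from -0.05 to 0.13 at 12 h, from -0.01 to 0.13 at 24 h and from -0.08 to 0.13 at 48 h. The retinoid medians ran from -0.02 to 0.07 at 12 h, from -0.01 to 0.06 at 24 h and from -0.03 to 0.09 at 48 h. Across all RA comparisons 27 of 130 list tests passed. The calls that held with an estimated correlation were those of the retinoid list at 12 h (adjusted p = 0.0364) and 24 h (adjusted p = 0.0377), and both were lost when a scan-day block was added (0.284 and 0.747). With replicate number as a block the retinoid calls at 48 h and in the mean (adjusted p = 0.468 and 0.0837) and the Hox call at 48 h (0.29) were lost. At 12 h the block follows the record pairs, but at 48 h it ties some arrays of different scan days. These losses, at 48 h and in a mean that includes 48 h, thus decide little.

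**Figure D3:**
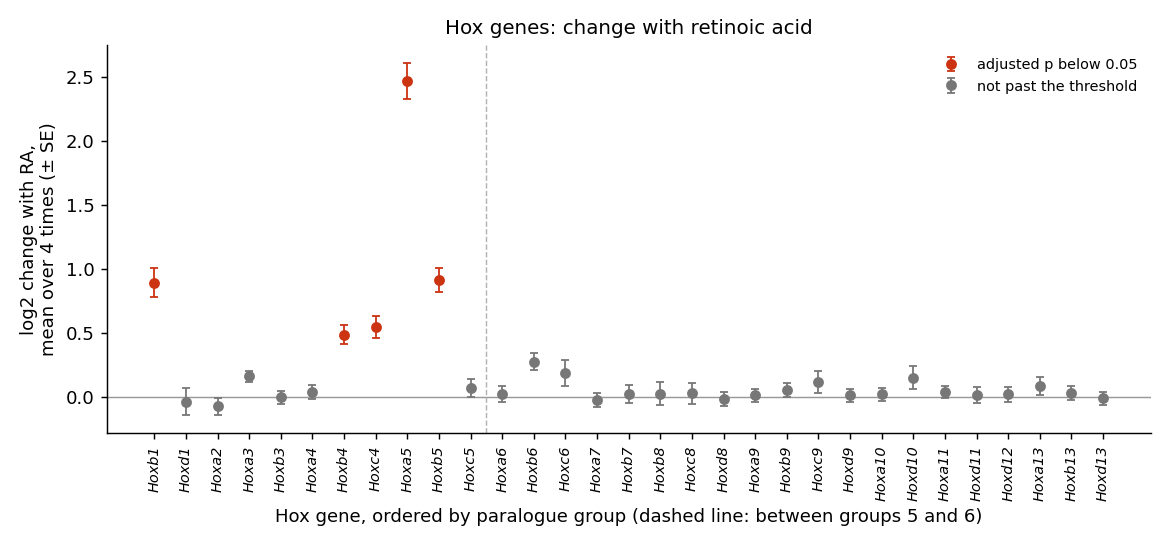
Mean log2 change with RA over the 4 times, with its SE (vertical axis), of each measured Hox gene by paralogue group (horizontal axis), with a dashed line between groups 5 and 6. Of the 11 genes of groups 1 to 5, 5 passed, with Hoxa5 at 2.47, and of the 20 genes of groups 6 to 13, 0 passed.

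Extracellular matrix genes lay lower with RA. Of 52 measured members, Col1a2 and Col5a2, both chains of fibrillar collagens, fell in the mean over times, Lama2 fell at 48 h, and none rose. Col5a2, named after its value was seen, fell by 0.33 log2 (adjusted p = 0.0222). Adjusted over the list alone, 8 fell and 1 rose in the mean, and 4 fell and 1 rose at 48 h. The list's median was -0.16 log2 at 6 h, -0.01 at 12 h, -0.05 at 24 h, -0.20 at 48 h and -0.10 in the mean, with camera adjusted p of 0.00128, 0.931, 0.0159, 3.25e-06 and 8.89e-06. The calls at 6, 24 and 48 h and in the mean were lost, with adjusted p = 0.511, 0.74, 0.353 and 0.175 with an estimated correlation. With all probe sets of a gene in place of 1 the 24 h call was lost (adjusted p = 0.063). A scan-day block gave adjusted p of 0.000205, 0.0181, 0.052 and 0.000468 for these, and a median at 48 h of -0.06. Within scan days the matrix median ran from -0.24 to -0.10 at 6 h, from -0.06 to -0.02 at 12 h, from -0.20 to -0.01 at 24 h and from -0.15 to -0.08 at 48 h. Of 24 smooth muscle and contractile genes 0 passed by limma, also when adjusted over the list alone, with Actg2 at -0.32 in the mean (adjusted p = 0.999). Their medians were -0.08 at 6 h, -0.12 at 48 h and -0.08 in the mean. Their camera adjusted p were 0.0343, 0.0202 and 0.00589, and with an estimated correlation the adjusted p = 0.553, 0.603 and 0.494. The 48 h call was lost with a scan-day block (adjusted p = 0.306), and within scan days their median ran from -0.13 to -0.06 at 6 h and from -0.08 to -0.03 at 48 h. Among the 48 h arrays, those of scan days 8 and 9 had lower smooth muscle and matrix lists (medians -0.36 and -0.31) than those of days 6 and 7. Days 8 and 9 held 2 RA arrays of 48 h, and days 6 and 7 held 1. Of 53 cell adhesion genes Vcam1 fell in the mean, and 6 fell when adjusted over the list alone. The list's median was -0.02 (camera adjusted p = 0.00528, adjusted p = 0.175 with an estimated correlation, 0.00553 with scan day as a block). A sign of RNA quality, the 3′ minus 5′ signal of Gapdh, differed between RA and control by 0.20 log2 (SD 0.288) over the 13 record pairs. An exact two-sided sign-flip test gave p = 0.0244, or 0.0976 by Benjamini-Hochberg over 4 measures. The difference for Actb was 0.15 (exact p = 0.0786, 0.157 adjusted).

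Among the lists of other cell types and processes, endothelial genes lay higher with RA, with medians of 0.11 log2 at 24 h, 0.13 at 48 h and 0.06 in the mean over 19 genes (camera adjusted p = 0.000561, 0.0317 and 0.0116). With an estimated correlation the adjusted p = 0.519, 0.603 and 0.494, and with a scan-day block the 48 h call was lost (adjusted p = 0.052). Replicate number as a block lost the calls at 48 h (0.374) and in the mean (0.0721), but it ties 48 h arrays not read as pairs. Within scan days their median ran from 0.09 to 0.18 at 24 h and from -0.01 to 0.26 at 48 h. Tal1, a factor of blood and endothelial progenitors, rose in the mean by at least 0.34 (SE 0.08, adjusted p = 0.0381, higher in 10 of 13 pairs), with its 48 h control mean below the 25th percentile, and 3 members did when adjusted over the list alone. Blood cell genes, 15 measured, had a median of 0.11 at 6 h (camera adjusted p = 0.0342, adjusted p = 0.511 with an estimated correlation, 0.031 with scan day as a block). It was 0.11 and 0.05 within the 2 scan days, and Car2 was the member that rose in the mean. Immediate early and heat shock genes, 38 measured, lay lower at 6 h, 24 h and in the mean (camera adjusted p = 0.0343, 0.0398 and 0.00238). With an estimated correlation the adjusted p = 0.511, 0.57 and 0.175, and with all probe sets of a gene the calls at 6 h (0.0726) and 24 h (0.0997) were lost. Their medians were -0.07, -0.07 and -0.06, and within scan days -0.11 and -0.10 at 6 h and -0.11 to -0.02 at 24 h. Btg1, a factor against proliferation, fell by 0.36 in the mean (SE 0.08, adjusted p = 0.0463, higher in 1 of 13 pairs), and 4 members fell when adjusted over the list alone. Cell cycle genes, 76 measured, lay lower at 12 h and in the mean (medians -0.09 and -0.04, camera adjusted p = 0.0104 and 0.0116). With an estimated correlation the adjusted p = 0.681 and 0.494, and with a scan-day block the adjusted p for the mean was 0.0598. The median was -0.12 and -0.03 within the 2 scan days of 12 h. Cdkn2b, an inhibitor of the cycle, was the member past the threshold, and it rose. Neural tube genes, 21 measured, lay lower at 12 h with a median of -0.02 and a mean of -0.19 (camera adjusted p = 0.0069, adjusted p = 0.681 with an estimated correlation, 0.0134 with scan day as a block). Their median was -0.01 and -0.16 within the 2 scan days, and Fabp7 was the member that fell at 24 h. These shifts stood beside the same difference in Gapdh signal of 0.20 log2.

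In 16 lists no RA comparison passed the camera test of limma. The lowest adjusted p over the 5 comparisons was 0.0919 for neural crest genes and for endoderm, 0.332 for neurons, 0.417 for glia, 0.501 for melanocytes, 0.178 for cartilage and bone, 0.439 for matrix proteases, 0.219 for Wnt signalling and 0.235 for TGF-beta and BMP signalling. It was 0.11 for FGF, hedgehog, Notch and ephrin signalling, 0.113 for p53 targets, 0.169 for surface ectoderm, 0.311 for macrophages, 0.12 for mesoderm and skeletal muscle, 0.0669 for glycolysis and 0.0603 for cholesterol synthesis. In alternatives, replicate number as a block called p53 targets at 48 h (adjusted p = 0.00163) and cholesterol synthesis at 6 h (0.0497), and all probe sets of a gene called glycolysis at 6 h (0.0318). The replicate number block ties 48 h arrays not read as pairs, so its p53 call decides little. Single members of these lists passed in the mean over times. Dlx5 of the neural crest list fell, Meox1 of the mesoderm list rose and Meox2 fell, and Wnt11 of the Wnt list rose and Dkk1 fell. Plat of the protease list rose, Bgn of the cartilage and bone list fell, and Slc2a3, a glucose transporter of the glycolysis list, fell by 0.36 log2 (SE 0.07, adjusted p = 0.00382). The difference of the RA effect between 48 h and 6 h passed for no list, with a lowest adjusted p of 0.134.

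The RA effects of different times were compared across probe sets, which are not independent replicates, and no arrays were shared between times. Pearson's r of the log2 differences was 0.277 between 6 and 12 h, 0.172 between 6 and 24 h, 0.252 between 6 and 48 h, 0.336 between 12 and 24 h, 0.214 between 12 and 48 h and 0.435 between 24 and 48 h. With a scan-day block the value for 6 and 48 h was 0.080, that for 12 and 48 h 0.159 and that for 24 and 48 h 0.549. All 19 probe sets called at 24 h had the same sign at 48 h, and all 34 called at 48 h had the same sign at 24 h, with 11 called at both times. Of the 34 called at 48 h, 31 had the same sign at 6 h and 32 at 12 h.

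Change with time in culture was read from the controls. Between 6 and 48 h the myosin heavy chains Myh3 and Myh7 of striated muscle rose by at least 2.91 (SE 0.36) and by 2.38 log2 (SE 0.40), with limma adjusted p of 1.68e-05 and 0.000499. The level of Myh3 at 6 h lay below the 25th percentile of the arrays, so its change may be understated. Signal shared with other myosin genes was not tested for the Myh7 probe set (98616_f_at). The troponins Tnnt2, Tnnc1 and Tnnt1 rose by 2.31 (SE 0.56), 2.23 (SE 0.42) and 2.02 (SE 0.28), with adjusted p of 0.00974, 0.00111 and 7.03e-05. Of 23 measured mesoderm and skeletal muscle genes 5 rose and 6 did when adjusted over the list alone (camera adjusted p = 0.00573, adjusted p = 0.125 with an estimated correlation). The matrix protein Tgfbi rose by 1.99 log2 (SE 0.28, adjusted p = 7.3e-05). Of 52 matrix genes 12 rose and 2 fell, or 21 and 4 when adjusted over the list alone (camera adjusted p = 0.00573, adjusted p = 0.555 with an estimated correlation). Cks2, which binds cyclin-dependent kinases, fell by 2.32 log2 (SE 0.19, adjusted p = 2.13e-07). Of 76 cell cycle genes 22 fell, such as Rrm2 (-1.15), Mad2l1 (-1.05) and Pcna (-0.58), chosen after their values were seen, and 1 rose, or 23 and 1 when adjusted over the list alone (camera adjusted p = 4.73e-11, adjusted p = 0.0331 with an estimated correlation).

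Among genes of the early neural crest, Crabp1 fell by 2.35 log2 (SE 0.33, adjusted p = 7.31e-05) between 6 and 48 h in controls, as did the transcription factors Msx2 (-1.60), Tfap2c (-1.55), Zic1 (-1.31) and Pax3 (-0.86), chosen after their values were seen. Of 37 measured members 11 fell and 0 rose by limma, or 12 and 2 when adjusted over the list alone (camera adjusted p = 8.13e-05, adjusted p = 0.0318 with an estimated correlation). Crabp2 fell by 2.55 log2 (SE 0.33, adjusted p = 2.96e-05), and Gsdme, which encodes a pore-forming gasdermin, by 2.64 (SE 0.34, adjusted p = 2.83e-05) on a probe set whose partner differed by 0.14 (adjusted p = 0.501). The tight junction genes Cldn6 (-2.46, SE 0.33) and Cldn7 (-2.45, SE 0.37) fell, and 6 of 21 surface ectoderm genes did, or 7 when adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.369 with an estimated correlation). Of 21 neural tube genes 4 fell, Sox2 (-1.98 log2) among them, or 7 with 1 rise when adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.555 with an estimated correlation).

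In total 1182 probe sets differed between 48 and 6 h controls (525 higher, 657 lower), 844 between 24 and 6 h (353 higher, 491 lower) and 674 between 12 and 6 h (329 higher, 345 lower). The limma F-test over the 3 times called 1599. The share of rises at 48 h was 44.4%, and after median centring 32.8% (361 higher, 739 lower), so the balance depended on scaling. The 6 h arrays filled scan days of their own, so time and scan day overlapped. Between 6 and 48 h controls the 3′ minus 5′ signal went from 1.72 to 2.00 log2 for Gapdh and from 1.49 to 1.94 for Actb (exact two-sided permutation p = 0.2 and 0.114, both 0.2 adjusted). Of 66 control probe sets 2 differed, by at most 0.97. With scan day as a random block the numbers were 570, 250, 179 and 865. The count for 12 h was 261 without control 1, 438 without control 2 or 350 without control 3 of 12 h, and 332 without control 2 or 353 without control 3 of 6 h. The count for 24 h was 550, 472 or 418 without control 1, 2 or 3 of 6 h and 542 without control 4 of 24 h. That for 48 h was 734, 733 or 740 without control 1, 2 or 3 of 6 h, and that of the F-test was 1062 without control 3 of 6 h. Within the 2 scan days that held both, 24 h controls differed from 12 h controls in 130 probe sets (51 higher, 79 lower) with 3 arrays each.

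**Figure D4:**
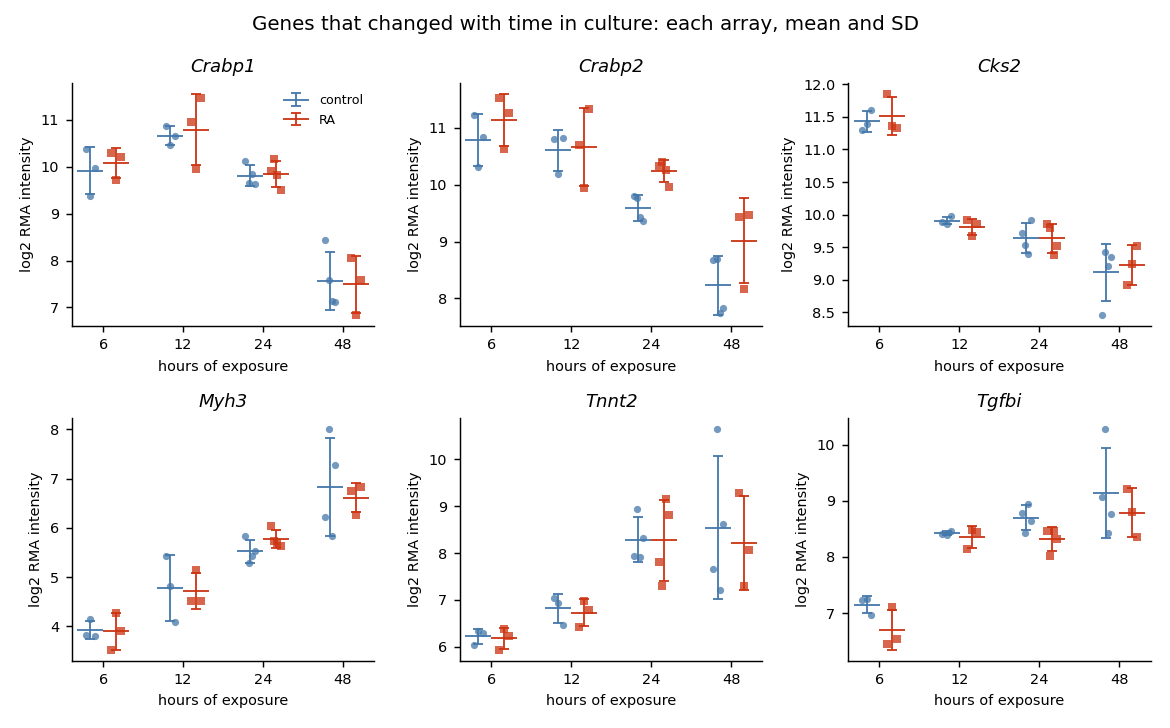
Log2 RMA intensity of Crabp1, Crabp2, Cks2, Myh3, Tnnt2 and Tgfbi (vertical axes) against hours of exposure (horizontal axes) in control and RA cultures, with a point for each array and the mean and SD of each group. In controls Crabp1 fell by 2.35 log2 between 6 and 48 h and Myh3 rose by at least 2.91.

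Between 6 and 48 h with RA, Myh3 rose by at least 2.71 log2 (SE 0.38) and Tgfbi by 2.09 (SE 0.30), with limma adjusted p of 5e-05 and 6.09e-05. Crabp1 (-2.58, SE 0.35), Cks2 (-2.28, SE 0.21) and Sox2 (-3.15, SE 0.41) fell, with adjusted p of 4.26e-05, 2.17e-07 and 2.44e-05. Csn3 fell by 2.08 log2 (adjusted p = 5.09e-07) between 6 and 48 h in controls and differed by -0.58 (adjusted p = 0.0759) with RA. Hoxa5 fell by 1.27 (adjusted p = 0.00503) in controls and differed by 0.00 (adjusted p = 0.996) with RA. Neither passed the test of that difference, given above as 1.51 and 1.26. Cell cycle genes fell in 22 of 76 cases and rose in 1, or 27 and 3 when adjusted over the list alone (camera adjusted p = 1.06e-08, adjusted p = 0.0803 with an estimated correlation). Neural crest genes fell in 10 of 37, also over the list alone (camera adjusted p = 0.000354, adjusted p = 0.0589 with an estimated correlation). Of 21 neural tube genes 7 fell and 1 rose, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00335, adjusted p = 0.439 with an estimated correlation). Of 52 matrix genes 11 rose and 2 fell, or 14 and 4 when adjusted over the list alone (camera adjusted p = 0.0396, adjusted p = 0.746 with an estimated correlation). In total 1458 probe sets differed (684 higher, 774 lower), 883 without RA 1 and 970 without RA 3 of 6 h, and 955 with scan day as a random block.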

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

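The tests of Hox paralogue groups, of the matrix list and of the chip lot were chosen after the results they measure were seen, and the count after cyclic loess was set beforehand. In 7 cases 1 array of 4 lay far from the other 3 of its group, judged by its gap to the nearest of them as a share of the group's range. At 24 h Etv2 was low in control 4 (gap 0.870 of the range), Tnnc1 in RA 2 (0.917), Cyp26a1 in RA 1 (0.838) and Csn3 in RA 2 (0.877), and Meox2 was high in RA 4 (0.855). At 48 h Lama2 (0.885) and 1 other gene (0.886) were high in control 2, the array with no RA partner on its scan day. Chance gives such a gap in about 1 group of 20, or 7.5 of the 150 tests made. The RA effect differed between 48 h and 6 h by 3.065 log2 for probe set 161049_at and by 1.674 for Igfbp3, by the direct limma test of that difference.

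The Hox genes that rose with RA belonged to paralogue groups 1 to 5, the end of the clusters expressed early and anteriorly. They were 5 of the 11 genes measured in these groups, and Hoxa5, at 2.47 log2, weighs most in the mean of the groups. Over all Hox genes measured, the mean change was 0.50 log2 (SD 0.749, 11 genes) in groups 1 to 5 and 0.05 (SD 0.076, 20 genes) in groups 6 to 13, with a two-sided permutation p of 0.00279 over 100000 resamples. The groups were divided on these same values and genes are not independent samples, so this p is no support for the division. Dim probe sets could hide a change in the later groups, but the 12 genes of groups 6 to 13 above the level of the dimmest 30% also had a mean of 0.05 (SD 0.086), which argues against dimness as the whole cause, while the permutation p among such genes, 0.0166, has the limits just given. A response that follows the place of a gene in the Hox cluster stays open as a hypothesis, and so does signal shared between paralogous probe sets, which was not tested.

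The extracellular matrix list lay lower with RA, and the median of the list was below 0 in 11 of 13 record pairs (mean -0.089, SD 0.111, exact two-sided sign-flip p = 0.0164). The size of the shift at 48 h may come in large part from control 2, since the median was -0.20 with this array and -0.057 without it, although the 3 pairs of 48 h, which leave it out, had medians from -0.149 to -0.082. RNA quality might also take part, since the 3′ minus 5′ signal of Gapdh was higher with RA by 0.196 log2 (sign-flip p = 0.0244, 0.0976 adjusted over 4 measures), but over the 13 pairs the list's shift and that signal had r = 0.238 (permutation p = 0.432) and rho = 0.066 (permutation p = 0.836), both 0.836 when adjusted over these 2 relations. Without the 2 pairs farthest from the median signal r was 0.025, so with 13 pairs RNA quality and RA cannot be told apart here. Lower matrix transcripts as a response to RA stay open as a hypothesis, since the list was picked for lying lower in these same arrays and its sign-flip p is no support for it.

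The 48 h arrays of scan days 8 and 9 (2 controls, 2 RA) stood apart from those of days 6 and 7 (2 controls, 1 RA), and a split along these days called 4687 probe sets where the split by RA called 34. An intensity-dependent difference of scan or hybridisation could produce this, and a rho of -0.293 between the difference and mean level across probe sets goes with a part of it, but 3861 were called after cyclic loess, which removes such trends, and this argues against it as the whole cause. The chip lot shared by days 5 and 8 was another candidate cause, and across probe sets the differences of the 2 days had r = -0.068, from -0.235 to 0.122 with 1 array left out, so it cannot be told apart from other features of those days. Differences between the embryos or explants of those days were not tested and stay open. The scan-day block removes this difference from the RA comparison at 48 h, and gave 99 calls.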

How the results depend on the processing

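The record pair block, the list tests, the RA target tests and the agreement between times with a scan-day block and the fit without scan day 5 were chosen after seeing the data, and the other alternatives were planned. Median centring, cyclic loess, leaving out the dimmest 30% and a robust intensity trend kept the count of every comparison within 1.5 times of its value. For named genes, leaving out 1 array lost a call 110 times and left call and direction the same 1033 times. Grouping 48 h control 3 with RA lost 24 calls, fits to only the groups compared 20 and array weights 9. Since that array had control levels of Cyp26a1 and Dhrs3, the losses from grouping it with RA would follow if its title is right. The cause of the changes in counts was not tested. The number of arrays and RMA's compression of dim signals limit small changes.

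With a block for replicate number the counts were 31 at 24 h, 127 at 48 h and 162 for the mean, 3 at 6 h, 4 at 12 h and 1 for the F-test between times. Equal numbers were not read as pairs at 12 h (r -0.035, 0.164 and 0.341) or 48 h (r 0.695, -0.344 and 0.001), although those of 12 h were also the record pairs. Array weights gave 141, 8, 42 and 15 at 6, 12, 24 and 48 h, 139 for the mean, 4 between times, and for controls 3147 by the F-test, 2462 at 12 h and 2306 at 24 h. Fits to only the groups compared gave 6, 7, 10 and 3 at the 4 times, 1 for 48 h minus 6 h and 559 for RA arrays at 48 h, with fewer residual degrees of freedom by construction. They were not run for the mean and the F-test between times, which use all groups. The scan-day block gave 55, 12, 50 and 99, 286 for the mean, 6 between times and 14 for 48 h minus 6 h. Scan day as a random block (consensus correlation 0.524) gave 865 by the F-test, 179, 250 and 570 for controls at 12, 24 and 48 h, and 955 for RA arrays. The record pair block gave 118, 17, 81 and 123, 365 for the mean, 11 between times and 18 for 48 h minus 6 h. With 48 h control 3 grouped as RA the counts were 7 at 48 h and 0 for both tests between times. Of 27 list calls 2 were left with an estimated correlation and 0 with that and a scan-day block.

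Leaving out 1 array at a time gave 1 to 2 calls at 6 h, 1 to 4 at 12 h, 10 to 17 at 24 h, 31 to 50 at 48 h, 57 to 94 for the mean, 2 to 3 between times and 2 to 5 for 48 h minus 6 h. For controls it gave 1062 to 1893 by the F-test, 261 to 474 at 12 h, 418 to 855 at 24 h and 733 to 1548 at 48 h, and 883 to 1365 for RA arrays. RA target tests past the threshold numbered 7 to 10.

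The reversals concerned RA targets that did not pass at those times. With array weights Crabp1 was -0.017 at 12 h and -0.138 at 24 h and Crabp2 -0.091 at 12 h. Crabp1 was -0.122 at 24 h without scan day 5, and Nr2f1 0.008 at 6 h after cyclic loess. Among fits without 1 array, Crabp1 ran from -0.112 to 0.392 at 6 h, -0.205 to 0.544 at 12 h, -0.066 to 0.159 at 24 h and -0.350 to 0.250 at 48 h. Crabp2 ran from -0.282 to 0.407 at 12 h, Nr2f1 from -0.099 to 0.022 and Stra6 from -0.040 to 0.140 at 6 h, and Tgm2 from -0.012 to 0.158 at 24 h.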

Other observations

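The tests of scan days at 48 h, the list tests on controls, the comparison of 24 with 12 h controls, the draws within record pairs and the looks at labels of single draws, at record pairs and at the number of arrays swapped were chosen after seeing the data, and the other tests were planned. In controls between 6 and 48 h, 5 of 26 genes of glycolysis and hypoxia rose and 1 fell, the same when adjusted over the list alone. The vasodilator peptide gene Adm rose by 1.28 log2 (adjusted p = 0.00391 by limma), the glycolytic enzyme gene Pfkp by 0.98 (adjusted p = 0.044) and P4ha2, a collagen prolyl hydroxylase, by 0.71 (adjusted p = 0.00122), and the glucose transporter gene Slc2a3 fell by 0.59 (adjusted p = 0.00435). The list as a whole did not pass camera (adjusted p = 0.242, 0.814 with an estimated correlation). Of 35 neuronal genes 2 rose and 4 fell, also over the list alone (camera adjusted p = 0.959): the intermediate filament gene Nefm rose by 1.23 (adjusted p = 0.00139), and the growth cone gene Gap43 fell by 1.20 (adjusted p = 0.0064).

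Among the 48 h arrays, those of scan days 8 and 9 differed from those of days 6 and 7 in 2223 probe sets with RA as a covariate (1104 higher, 1119 lower). On days 8 and 9 the keratins Krt18 (-1.97 log2, adjusted p = 0.00398 by limma) and Krt8 (-1.78, adjusted p = 0.00292) of simple epithelia and Actg2 (-1.54, adjusted p = 0.0125), a smooth muscle actin, were lower. The protease inhibitor gene Tfpi2 (1.95, adjusted p = 0.00974) and the metalloprotease gene Tll1 (1.68, adjusted p = 0.00634) were higher. Of 24 smooth muscle genes 7 were lower (median -0.36) and of 52 matrix genes 13 (median -0.31), each with a camera adjusted p of 0.00549 and an adjusted p = 0.841 with an estimated correlation.

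Other splits of the same arrays were counted, the real one included. At 24 h 1 of 35 splits gave as many calls as the real 19, with 0 as the highest other, so chance is excluded there over all splits, and among the 8 splits that part all 4 pairs, too few for a share below 0.05, the highest other was also 0. At 48 h 10 of 35 gave as many as the real 34, so over all splits chance is not excluded. Among the 8 splits that part all 3 record pairs of 48 h, too few for a share below 0.05, the real 34 was the highest and the highest other was 10. The highest of the 35 splits, 4687, parted scan days 8 and 9 from days 6 and 7 and points to a structure of the samples, and with scan day as a block 99 passed. For the mean over times 3 of 100 labellings gave as many as 70, with a highest of 375, which excludes chance at a share below 0.05 over such labels. For the RA target tests 1 of 100 did (real 9, highest other 2), for the gene lists 1 of 100 (real 27, highest other 23) and for the agreement between times 1 of 100 (real 0.264, highest other 0.176), so chance is excluded for each over labels drawn freely within a time. For the difference between times 13 of 100 gave at least 2 calls (highest 2168), and for 48 h minus 6 h 19 of 100 (real 2, highest 2826), so chance is not excluded. In 4 draws the 3 arrays of 48 h called RA were those of scan days 6 and 7. These held the highest counts of the mean and of both tests between times, all 4 reached the real count in the latter, and with scan day as a block 6 and 14 probe sets passed.

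Those draws did not keep record pairs, and 100 labellings that swap control and RA within record pairs were counted too. Within pairs 1 of 100 was as high for the mean (highest other 9), 1 for the RA target tests (highest other 3), 1 for the agreement (highest other 0.187), 2 for the gene lists (highest other 28) and 2 for 48 h minus 6 h (highest other 2). At a share below 0.05 chance labels within pairs are excluded for these. For 48 h minus 6 h a draw equalled the real count and the free draws did not exclude chance, so its number of calls stays uncertain. For the difference between times 7 of 100 were as high (highest other 23), so chance labels within pairs are not excluded there. For the gene lists these draws bear on the number of calls alone. Chance labels gave up to 28 list calls within pairs and 23 in free draws, beside the real 27, so single list calls gain no support.

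For controls, the F-test had 1 of 100 labellings as high (real 1599, highest other 326) and 24 against 6 h 1 of 35 splits (real 844, highest other 305). Chance is excluded for both over labels drawn freely. The 6 h controls had scan days of their own, so a difference between scan days could also make the real labels the highest. For 48 against 6 h 2 of 35 were as high (real 1182, highest other 1231). The split with 1231 parted 3 of the 4 controls of 48 h from all 3 of 6 h, so it kept most of the contrast of time, and the highest among splits that swapped 1 or 2 arrays per group was 83. The splits were too few for a share below 0.05 in the other comparisons. These were RA at 6 h and at 12 h (each 1 of 10, real 3, highest other 0), controls at 12 h (1 of 10, real 674, highest other 0), RA arrays at 48 h (1 of 10, real 1458, highest other 0) and 24 against 12 h controls within 2 scan days (1 of 6, real 130, highest other 0).

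One hypothesis was that RA slows the change that culture brings, which would make RA effects run against the change of controls with time. Across probe sets the RA effect at 48 h had r = 0.051 with the change of controls from 6 to 12 h, and 27 of 35 labellings of the 48 h arrays gave a value as low (-0.288 to 0.254 among the others, and 0.014 with scan day as a block). The RA effect at 24 h had r = -0.067 with the change of controls from 6 to 48 h, and 21 of 70 labellings were as low (-0.267 to 0.267). Both comparisons used different controls for the 2 sides. By the bound written beforehand neither value speaks for the hypothesis, but both lay within the spread of the labellings, which is too wide to rule it out.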
